A study of Nitratidesulfovibrio vulgaris str. Hildenborough with 30 samples.

How the data were processed

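The data were 30 arrays of the sulfate-reducing bacterium Desulfovibrio vulgaris Hildenborough, grown in batch culture in LS4D, a defined medium. Per the labels, each array carried Cy5-labelled total RNA of the sample in channel 1 and Cy3-labelled genomic DNA of the strain in channel 2, with the same dye orientation throughout. Genomic DNA here is a common reference that corrects each spot for the amount of probe printed, and it is not a sample of any group. The groups and replicate numbers were taken from the sample titles. They form 10 groups of 3 arrays: untreated cells and cells given 250 mM NaCl, each at 0, 30, 60, 120 and 240 min. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may in part be technical.

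The authors deposited 1 value per spot and array, in a table of 9216 numbered spots. The deposited values are log ratios of the channels. The image analysis, background correction, filtering and normalization that the authors applied are not given in the sources used here. The log base is not stated either, and values are therefore given in log units. Base 10 was excluded by the range of the values: the widest array spanned 16.9 log units, while a pair of channels with 65535 levels each spans at most 9.63 decades. Base 2, under which 1 log unit is a 2-fold change, and the natural logarithm both remain possible. The direction of the ratio is likely RNA over genomic DNA. The basis is that RNA is channel 1 on all arrays and that the values were skewed to the right on each of them, with a skewness of 0.63 to 0.93. Under the opposite direction, "higher" and "lower" would swap in every statement. The deposited medians of the arrays ran from -2.97 to -0.90, so the values had not been centred.

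The table numbers its spots and does not pair the numbers with genes, and no table used here does so. Genes could therefore not be named, spots for controls could not be told from spots for genes, and the planned tests of 32 gene lists and the planned check of the ratio's direction on abundant transcripts could not be run. Because of this the named items were limited to 2 spot pairs with a higher and 2 with a lower value. They follow the rule fixed before the data were examined for the average over 30 to 240 min: the largest effects with an adjusted p below 0.05 whose means differed in the same direction at all 4 of these times. That rule would otherwise have named 8 in each direction.

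Duplicate spots were found from the values. Rows lying 4608 apart had mean values that correlated at 0.99 across spots, while the next highest correlation at any other offset, 2304, was 0.44. Each such pair of spots was averaged, and a spot present alone was used as it was. Of the array values, 96.1% had both spots, and the median SD between duplicate spots was 0.147 log units. This left 3637 spot pairs with a value on at least 1 array, of which 3369 had values on all 30. The other 971 positions held no value in either spot. If a gene has several probes, its spot pairs were counted separately. Arrays held between 6834 and 7081 spots with a value. No arrays were identical. Since these are arrays, precision is limited by their number, not by a count depth.

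Each array was centred on its median over spot pairs. A model with 1 mean per group was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the 10 groups shared 1 residual spread per spot pair, with 20 residual and 6.99 prior degrees of freedom. NaCl was compared with untreated cells at each time, at each later time beyond the 0 min difference, and on average over 30 to 240 min. Moderated F tests asked whether the NaCl effect differed between 30, 60, 120 and 240 min, and whether untreated cells changed over time. Tests were two-sided. A spot pair was tested where each group involved had at least 2 of its 3 values, and adjusted p-values are Benjamini-Hochberg values over the spot pairs tested in that comparison, with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9.

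The model was tested on simulated data built from the real means, residual spreads and missing values of 3597 spot pairs, with 200 of them changed at 60 min in each of 20 simulations. It recovered 16.7% of changes of 0.5 log units, 75.9% of changes of 1 log unit, 93.5% of changes of 1.5 and 97.4% of changes of 2. Of all calls 4.77% were false, and the unchanged 0 min comparison gave at most 1 call. Spot pairs were simulated as independent, which real ones are not. The noise was normal, with the same spread on all arrays and no replicate or batch structure. Fewer spot pairs were changed than were called in the real data at 60 min. The rates therefore hold for such simulated data and may differ for the real arrays.

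Arrays of NaCl and untreated cells that share a time and a replicate number did not deviate together: only 6 of the 15 such pairs had residuals correlating above 0.1, with a range from -0.65 to 0.30. Between times, the residuals of NaCl arrays with the same number correlated above 0 in 25 of 30 cases, with a median of 0.208, and those of untreated arrays had a median of 0.025. The numbers were therefore not treated as pairs of NaCl and untreated arrays, and the fit with the replicate number as a block is given among the alternatives. The alternatives fixed before the data were examined were no centring, quantile normalization, only spot pairs complete on all arrays, removal of the 25% of spot pairs with the lowest mean value, a fit on the compared groups alone, an intensity trend with a robust prior, array weights, a replicate block, the culture (treatment and replicate number) as a random block, duplicate spots kept apart, a minimum change of 1 log unit, and leaving out each array in turn. A further 3 were chosen after seeing the data: all 15 untreated arrays as the control, NaCl replicate 2 left out at all times, and the 0 min arrays of replicate 1 left out.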

Results

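Transcript levels in Desulfovibrio vulgaris Hildenborough, an anaerobic bacterium that respires sulfate, were measured over 240 min after addition of 250 mM NaCl and in untreated cells at the same times. The data comprised 30 arrays in 10 groups of 3, covering 0, 30, 60, 120 and 240 min. Each value is the log ratio of RNA to genomic DNA for a pair of duplicate spots, centred on the array's median. The spots carry numbers and no gene names, so the response is described by its size, direction and timing over all spot pairs and by the 4 spot pairs with the largest average changes over 30 to 240 min. Effects are NaCl minus untreated, in log units of an unstated base. "Higher" means more RNA relative to genomic DNA, which is the likely direction of the deposited ratio.

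The 0 min comparison gave the baseline between the cultures. None of the 3565 spot pairs tested differed at 0 min by limma with Benjamini-Hochberg adjustment, and 136 had an unadjusted p below 0.05. The root-mean-square effect beyond measurement error was 0.057 log units, against 0.407 at 30 min. Array weighting, in contrast, called 147 spot pairs at 0 min, and leaving out the 0 min arrays of replicate 1, a choice made after seeing the data, called 73.

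At 30 min, NaCl changed 346 of 3528 spot pairs, or 9.81%, of which 203 were higher and 143 lower. The spot pairs that were higher had a median effect of 1.01 log units and a largest effect of 4.15. Those that were lower had a median of -0.87 and a largest effect of -1.97. Changes of at least 1 log unit numbered 106 upward and 38 downward. The count at 30 min depended on single arrays: it was 560 without NaCl replicate 2, 124 without NaCl replicate 3, 140 without NaCl replicate 1, and 228, 184 and 201 without untreated replicates 1, 2 and 3.

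By 60 min the response covered 1024 of 3542 spot pairs, or 28.9%, with 612 higher and 412 lower. The median effects of these were 0.94 and -0.77 log units. The count fell to 587 without NaCl replicate 1 and to 580 without NaCl replicate 3, and was 370 when only the 6 arrays of this time were fitted.

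On centred values the largest number of changed spot pairs was found at 120 min, when 1483 of 3503, or 42.3%, differed from untreated cells. Of these, 810 were higher and 673 lower, with median effects of 0.96 and -0.91 log units. At least 1 log unit separated the groups for 378 spot pairs that were higher and 285 that were lower. The root-mean-square effect beyond error also peaked at this time, at 0.753 log units, compared with 0.592 at 60 min and 0.614 at 240 min. With NaCl replicate 2 left out at all times, a choice made after seeing the data, the count was 1527 at 60 min and 1517 at 120 min. Without centring it was 690 at 120 min and 2396 at 240 min, and untreated cells at 120 min themselves differed from the other untreated times at 353 spot pairs.

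At 240 min, 1130 of 3536 spot pairs, or 32.0%, differed from untreated cells of the same age, 633 higher and 497 lower. Effects of at least 1 log unit were measured for 290 upward and 143 downward. Neither the 120 min nor the 240 min count moved by more than 1.5 times when any single array of the compared groups was left out.

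**Figure D1:**
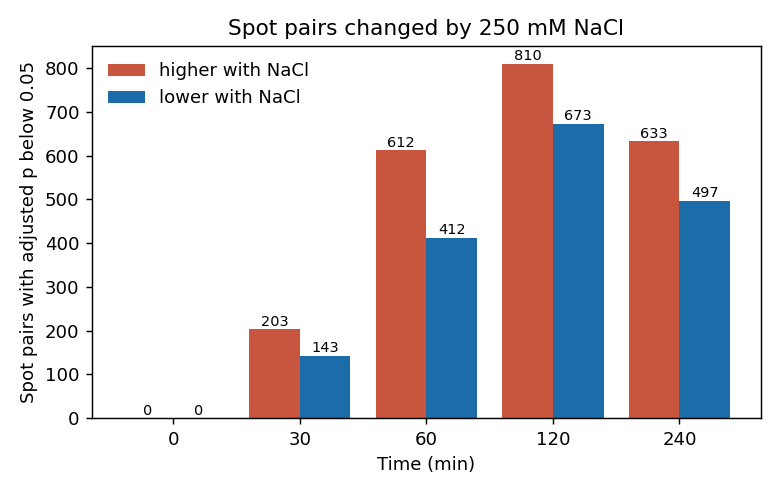
Number of spot pairs (y axis) with an adjusted p below 0.05 that were higher or lower with NaCl at each time in min (x axis), 3 arrays per group. The count was 0 at 0 min, rose to 810 higher and 673 lower at 120 min, and was 633 higher and 497 lower at 240 min.

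These directions are relative to the median spot pair of each array. Without centring, the array medians themselves differed, with NaCl minus untreated at -0.35 log units at 0 min, -0.28 at 30 min, -0.58 at 60 min, -0.42 at 120 min and -1.20 at 240 min. At 240 min the deposited array medians averaged -2.50 ± 0.41 with NaCl and -1.31 ± 0.42 without (SD, n = 3), and an exact two-sided permutation test gave p = 0.10, the smallest that 3 against 3 arrays allow. The other times had exact permutation p-values of 0.40, 0.40, 0.30 and 0.20. On the uncentred values the split between higher and lower was 20 to 8 at 30 min, 55 to 529 at 60 min, 147 to 543 at 120 min and 17 to 2379 at 240 min. Quantile normalization gave 184 to 189, 478 to 487, 692 to 716 and 547 to 573 at the same times, so the excess of higher over lower calls did not hold under it. This method gives all arrays the same distribution, which itself favours balanced calls. It therefore cannot decide whether the excess is real.

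Changes persisted in direction. Of 3480 spot pairs tested at all 4 times from 30 to 240 min, 2061 were called at 1 or more times, 140 at all 4, and 28 were called in opposite directions at different times. Higher values at all 4 times were found for 103 spot pairs, and lower values for 36. The times share no arrays, although the residuals of NaCl arrays with the same replicate number correlated above 0 in 25 of 30 cases between times, with a median of 0.208. Between 30 and 60 min, 165 spot pairs were higher at each time where independent lists would share 35.1, and 91 were lower where 16.8 would be shared. Between 120 and 240 min, 451 were higher at each time against 144.8 for independent lists, and 383 were lower against 95.2. Only 1 spot pair was called in opposite directions at 120 and 240 min, compared with 19 at 30 and 240 min. Across spot pairs, which are not independent replicates, the effects correlated at 0.73 between 30 and 60 min, 0.75 between 60 and 120 min, 0.83 between 120 and 240 min and 0.42 between 30 and 240 min. The 0 min effects correlated with those of later times at between -0.08 and 0.05.

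Averaged over 30 to 240 min, NaCl changed 2092 of 3480 spot pairs, or 60.1%, with 1139 higher and 953 lower. Most of these average effects were modest: the medians were 0.55 and -0.50 log units, and 259 spot pairs reached 1 log unit, 184 upward and 75 downward. On uncentred values 159 were higher and 2117 lower, and with quantile normalization 985 were higher and 1050 lower.

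The largest average rise belonged to spots 1580 and 6188, at 3.49 ± 0.12 log units (SE, limma adjusted p = 3.4e-18). Their effect was -0.06 at 0 min, 2.41 at 30 min, 3.56 at 60 min, 4.0 at 120 min and 3.98 at 240 min, with an SE of 0.24 at each time. In untreated cells the same spots went from 1.46 ± 0.13 at 0 min to 0.83 ± 0.23 at 240 min (SD, n = 3), while NaCl-treated cells went from 1.39 ± 0.29 to 4.81 ± 0.19. Spots 1517 and 6125 came next, with an average of 3.41 ± 0.13 (SE, limma adjusted p = 1.7e-17). Their effect was already 4.15 at 30 min, and was 3.50 at 60 min, 3.69 at 120 min and 2.32 at 240 min, with an SE of 0.26.

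The largest average fall was that of spots 502 and 5110, at -1.99 ± 0.21 log units (SE, limma adjusted p = 9.6e-09). Their level with NaCl was -0.97 ± 0.23 at 0 min, -0.93 ± 0.77 at 30 min, -1.36 ± 0.75 at 60 min, -1.92 ± 0.78 at 120 min and -2.05 ± 0.41 at 240 min (SD, n = 3). In untreated cells it was -0.98 ± 0.42 at 0 min, 1.04 ± 0.52 at 30 min, 1.39 ± 0.31 at 60 min, 0.55 ± 0.35 at 120 min and -1.28 ± 0.72 at 240 min. The effect was -2.75 at 60 min and -0.77 at 240 min, where it did not pass the threshold (limma adjusted p = 0.16). Spots 4489 and 9097 averaged -1.82 ± 0.13 (SE, limma adjusted p = 7.0e-12), with an effect of -0.78 at 30 min, -1.60 at 60 min, -2.34 at 120 min and -2.55 at 240 min. The 30 min effect only just passed the threshold (limma adjusted p = 0.049). NaCl replicates 1, 2 and 3 of these spots were at 0.12, 1.19 and 0.05 at 30 min and at -0.26, 0.78 and -0.13 at 60 min. Untreated cells held these spots between 1.23 ± 0.15 and 1.74 ± 0.21 (SD, n = 3). All 4 averages kept their direction and stayed past the threshold in each of the 36 alternatives computed for them. Over these, the average ranged from -2.60 to -1.71 for spots 502 and 5110 and from -2.43 to -1.77 for spots 4489 and 9097. The order of these falls therefore did not hold in all alternatives.

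**Figure D2:**
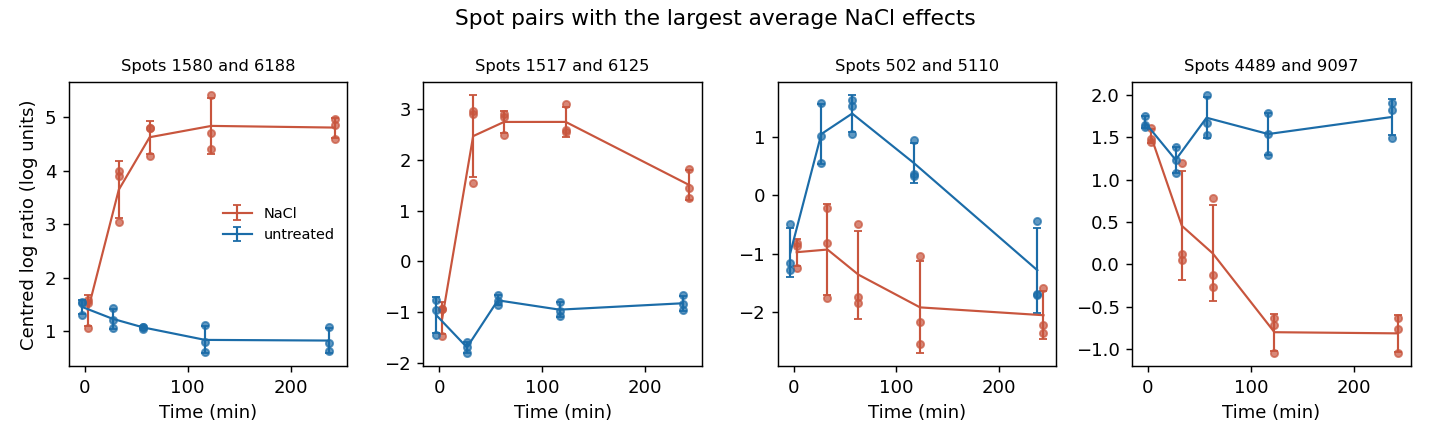
Centred log ratio in log units (y axis) over time in min (x axis) for the 2 spot pairs with the largest average rise and the 2 with the largest average fall with NaCl; points are arrays, lines and bars are the mean and SD of 3 arrays. Spots 1580 and 6188 stay above untreated cells through 240 min. Spots 502 and 5110 rise in untreated cells at 30 and 60 min, while with NaCl they are at -0.93 at 30 min and fall to -2.05 at 240 min.

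Whether the NaCl effect itself differed between 30, 60, 120 and 240 min was tested in 1 model. It differed for 364 of 3480 spot pairs (moderated F test, adjusted p below 0.05), and 652 were called without the 60 min NaCl array of replicate 2. Uncentred values gave 20 calls and array weights 1406. Spots 1580 and 6188 (adjusted p = 0.0071), spots 1517 and 6125 (0.0096) and spots 4489 and 9097 (0.0052) were among the 364, and spots 502 and 5110 were not (0.076). Pairwise contrasts, chosen after seeing the data, found 327 spot pairs whose effect changed from 30 to 240 min. Of these, 265 had moved farther from 0 and 62 nearer to it. From 60 to 120 min the effect changed for 81 spot pairs, 65 of them farther from 0. No spot pair passed the threshold from 30 to 60 min or from 120 to 240 min by limma, where 335 and 348 had an unadjusted p below 0.05.

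Subtracting the 0 min difference from each later effect left 94 changed spot pairs at 30 min, 465 at 60 min, 977 at 120 min and 442 at 240 min. The higher and lower counts were 61 and 33, 274 and 191, 514 and 463, and 253 and 189. On uncentred values the totals were 9, 14, 82 and 197, split into 9 and 0, 12 and 2, 58 and 24, and 8 and 189, and quantile normalization gave 201 and 219 at 240 min, so the balance at 240 min turned under both. This contrast carries the spread of 4 groups, with a root-mean-square error of 0.36 log units against 0.25 to 0.26 for a single time. Fitting the compared groups alone gave 23 at 30 min and 95 at 60 min, while array weights gave 771, 1363, 1853 and 1317 at 30, 60, 120 and 240 min. Single arrays also moved the counts by over 1.5 times, except at 120 min. The 30 min count was 37, 263 and 35 without NaCl replicates 1, 2 and 3 of that time, 42 and 54 without untreated replicates 1 and 2 of that time, 42 without the 0 min array of NaCl replicate 2, and 57 and 51 without those of untreated replicates 2 and 3. At 60 min it was 193, 1076 and 188 without NaCl replicates 1, 2 and 3, 300 without untreated replicate 3 and 239 without the 0 min array of NaCl replicate 2. The 240 min count was 250 and 280 without NaCl replicates 1 and 3, 272, 291 and 241 without untreated replicates 1, 2 and 3, and 252 and 265 without the 0 min arrays of NaCl and untreated replicate 2.

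Centred values of untreated cells also differed between times. The F test across the 5 untreated groups called 396 of 3522 spot pairs, and 102 without 120 min. Uncentred values gave only 5 calls, and array weights 2143. Leaving out single untreated arrays gave 133 to 439, with 236, 133 and 170 without replicates 1, 2 and 3 at 120 min, 234, 238 and 227 without those at 30 min, 213 and 231 without replicates 2 and 3 at 0 min, and 256 and 236 without replicates 1 and 2 at 240 min. Against untreated 0 min, 226 spot pairs differed at 30 min, 34 at 60 min, 312 at 120 min and 20 at 240 min. Set against the mean of the other 4 untreated times, 120 min differed at 353 spot pairs, 0 min at 159, 30 min at 58, 240 min at 21 and 60 min at 4. With all 15 untreated arrays as a common control, chosen after seeing the data, NaCl changed 0 spot pairs at 0 min, 754 at 30 min, 1619 at 60 min, 1667 at 120 min and 1483 at 240 min.

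The 3 NaCl arrays of a time did not respond equally. For each NaCl array, its difference from the untreated arrays of the same time was regressed on a reference effect taken from the other replicates at the other times. A slope of 0 means no response and a slope of 1 the response of that reference. The reference of replicate 2 held only replicates 1 and 3, while theirs included replicate 2, so the slopes are not on a common scale. Smaller gaps between replicates, as at 120 and 240 min, may stem from the reference. An untreated array was compared with the other untreated arrays of its time, and its reference held all replicates. At 30 min the slopes were 0.75, 0.13 and 0.53 for replicates 1, 2 and 3, and at 60 min they were 1.25, 0.40 and 1.19. The corresponding slopes were 1.33, 1.10 and 1.31 at 120 min, and 0.97, 0.70 and 0.97 at 240 min. At 0 min the NaCl arrays lay between -0.10 and 0.05, and untreated arrays of all times between -0.07 and 0.08. With 1 array per replicate and time, the difference of replicate 2 from the others was not tested within a time. Leaving it out at all times gave 685 changed spot pairs at 30 min, 1527 at 60 min, 1517 at 120 min and 1220 at 240 min.

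**Figure D3:**
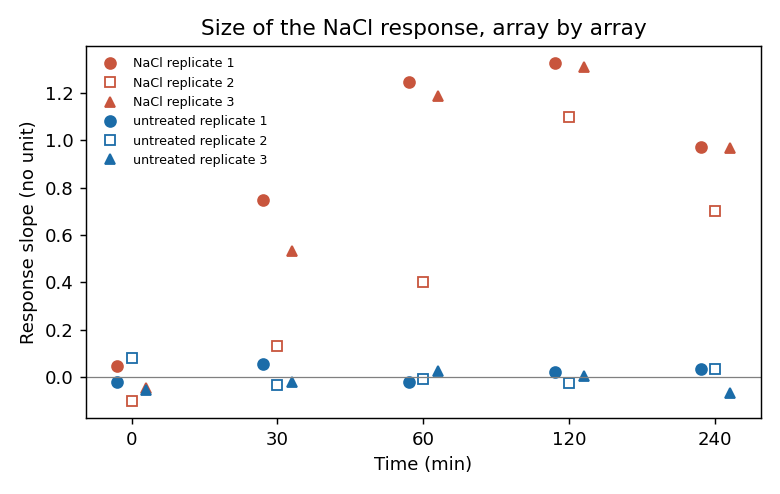
Slope of each array's difference from untreated cells on the average NaCl effect of other times (y axis, no unit) against time in min (x axis). There are 15 NaCl and 15 untreated arrays. For NaCl arrays the average leaves out their own replicate, and for untreated arrays it holds all replicates. NaCl replicate 2, drawn as open squares, has the lowest slope at 30, 60, 120 and 240 min, with 0.13 and 0.40 at 30 and 60 min. Its reference leaves out replicate 2, unlike those of the other NaCl replicates, so its slopes are not on their scale.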

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

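The pairwise contrasts between times and the splits that move a replicate number as a whole were chosen only after the main results had been seen. The NaCl effect differed between 30, 60, 120 and 240 min for 364 spot pairs, by a test of the difference itself. It changed from 60 to 120 min for 81 spot pairs, from 60 to 240 min for 68 and from 30 to 240 min for 327. Among the spot pairs with the largest average effects, a difference between times was found for spots 1580 and 6188 (moderated F test, adjusted p = 0.00711), spots 1517 and 6125 (0.00960) and spots 4489 and 9097 (0.00523). This test asks for any difference, and the courses were read from the mean effects. The rise of spots 1580 and 6188 built up to 120 min. That of spots 1517 and 6125 was smallest at 240 min, and the fall of spots 4489 and 9097 deepened.

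Each count was set against other splits of the same arrays. At a single time, 3 against 3 arrays make 10 splits, which is too few for a share under 0.05. The real split gave 346 calls at 30 min, 1024 at 60 min, 1130 at 240 min and 1483 at 120 min, in each case the only 1 of the 10 to reach that number, while the highest of the other splits gave 0, 218, 0 and 0 in the same order. At 0 min all 10 splits gave at least the 0 calls of the real one, and the highest gave 432, which points to a structure of these 6 arrays. For the average over 30 to 240 min, 1 of 100 splits, the real one with 2092 calls, was as large, and the highest other gave 850, so chance is excluded if arrays of different times vary independently. For untreated cells, whose arrays were exchanged between the times, 1 of 100 splits reached the real 396, and the highest other gave 27, so chance is excluded there on the same condition. Beyond the 0 min difference, 4 of 100 splits reached the 977 calls at 120 min and 3 of 100 the 442 at 240 min, with 1487 and 527 as the highest others. The other splits as large, 3 at 120 min and 2 at 240 min, had all kept the real NaCl and untreated arrays of that time together. Splits that had not gave at most 227 and 93 calls. These shares thus depend on how often the splits kept that time together and on how the 0 min arrays were relabelled. They do not decide on chance, even if arrays of different times vary independently. For the 94 calls at 30 min and the 465 at 60 min, 7 of 100 splits were as large in each case, the highest others being 419 and 1085. Chance is not excluded, but splits that kept the real arrays of that time together weigh on these shares too. For the difference between times, 6 of 100 splits reached 364, the highest other giving 1290. This share cannot decide on chance. A split that keeps the real arrays together at only some of the times creates a difference between times by itself. In that test all 5 other splits as large had kept the real NaCl and untreated arrays together at 1 or more times, and splits that kept none gave at most 1 call. Of the 6 other splits as large beyond the 0 min difference at 30 min, all 6 had kept them together. At 60 min 4 of 6 had, and a split that had not gave up to 992 calls. NaCl arrays with the same replicate number deviated together between times, so the condition of independent times was not met for counts that use them. Moving each number as a whole through all times leaves 10 splits, too few for a share under 0.05: the highest other gave 23 calls for the average, against 2092, and 0 for the difference between times and for each count beyond the 0 min difference.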

How the results depend on the processing

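Quantile normalization, spot pairs complete on all arrays, removal of the lowest 25% by mean value, the trend with a robust prior, duplicate spots kept apart, the replicate block and the culture block moved none of the 12 counts by more than 1.5 times. The replicate block gave 384, 1048, 1500 and 1169 calls at 30, 60, 120 and 240 min, and it changed 3 of the 44 calls of the named spot pairs, all of spots 502 and 5110, which then passed the threshold at 240 min (limma adjusted p = 0.040), at 30 min beyond the 0 min difference (0.0066) and for the difference between times (0.0068). The numbers do not pair NaCl with untreated arrays: 10 of the 30 arrays correlated best with their own number, the number expected by chance for 3 candidates. The culture block, with an estimated correlation within a culture, gave 354, 1030, 1495 and 1148.

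Without centring, calls fell to 28 at 30 min, 584 at 60 min and 690 at 120 min and rose to 2396 at 240 min. They fell to 9, 14, 82 and 197 beyond the 0 min difference at the 4 times, to 20 for the difference between times and to 5 for untreated cells over time. Array weights gave 147 at 0 min, 944 at 30 min, 1797 at 240 min, 771, 1363, 1853 and 1317 beyond the 0 min difference at 30, 60, 120 and 240 min, 1406 for the difference between times and 2143 for untreated cells. Requiring 1 log unit left 144, 366, 663 and 433 at 30, 60, 120 and 240 min and 259 on average, by its construction. The compared groups alone gave 370 at 60 min, 23 and 95 beyond the 0 min difference at 30 and 60 min, and 793 for untreated cells. For the other changes the cause was not tested.

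Of the alternatives chosen after seeing the data, all 15 untreated arrays as control gave 754 at 30 min and 1619 at 60 min. NaCl replicate 2 left out at all times gave 685 at 30 min, 238 and 908 beyond the 0 min difference at 30 and 60 min, and 637 for the difference between times. The 0 min arrays of replicate 1 left out gave 73 at 0 min and 199 and 763 beyond the 0 min difference at 30 and 60 min.

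Leaving out 1 array at a time gave 124 to 560 at 30 min and 580 to 1479 at 60 min. Beyond the 0 min difference the ranges were 35 to 263 at 30 min, 188 to 1076 at 60 min and 241 to 520 at 240 min. They were 250 to 652 for the difference between times and 133 to 439 for untreated cells. The counts at 0, 120 and 240 min, at 120 min beyond the 0 min difference and on average stayed within 1.5 times of the main value. The planned gene list tests at 5 times, with their alternatives, were not run because the spots could not be matched to genes. Signal over background is unknown, so no limit from dim spots can be given.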

Other observations

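Of the tests below, the exchange of arrays, the array batch, the time profile of the mixture, the removal of the 0 min axis, the mixture with the ratio turned and the position test of the spot layout were chosen only after the result had been seen. The axis removal was devised once the first result on a delay was known, and a delay was from then on also required to hold with the axis removed. Measured against their own 0 min arrays, NaCl-treated cells changed at 622 spot pairs by 30 min, 1050 by 60 min, 1265 by 120 min and 1135 by 240 min. In the last, 582 were higher and 553 lower. Untreated cells changed at 226 by 30 min, 34 by 60 min, 312 by 120 min and 20 by 240 min, the last with 4 higher and 16 lower. Both courses lean on 0 min arrays that were not uniform.

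The 6 arrays at 0 min fell into sets that cross the groups: centred levels of untreated replicate 1 correlated at 0.98 with NaCl replicate 3 and 0.97 with NaCl replicate 2, but at 0.95 and 0.93 with untreated replicates 2 and 3, and NaCl replicate 1 correlated best with untreated replicate 2, at 0.98. A split that exchanges the replicate 1 arrays called 432 spot pairs, where the highest of the other splits called 1. A bias that depends on the ratio level is argued against, since a smooth curve explained 0.024 of the variance of the difference between the sets. Noise of single spots is argued against too, since first and duplicate spots gave differences correlating at 0.81. Position effects that both spots share are not excluded, because the place of the duplicates on the slides is unknown. An exchange of labels and a batch of arrays that crosses the groups both remain open, and either may apply: the same axis appeared at 60 min, with correlations of 0.38, -0.33 and -0.08 for untreated replicates 1, 2 and 3 and of -0.40, 0.57 and -0.45 for NaCl replicates, and at 120 min among NaCl replicates (-0.25, 0.42 and -0.32). It was weaker at 240 min (-0.23 to 0.21 over both groups) and near 0 at 30 min in both groups and at 120 min in untreated cells (-0.03 to 0.06), so a batch would have to affect only some times.

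NaCl replicate 2 responded least at 30 and 60 min, and untreated RNA mixed into the array would cap the falls more than the rises. With the share set by the rises and values read in base 2, the median fall of replicate 2 at 30 min was larger than a mixture predicts by 0.21 log units (difference -0.21, 95% bootstrap interval -0.31 to -0.09). With the ratio turned the difference was -0.25 (-0.36 to -0.15). At 60 min it was 0.0703 (-0.0017 to 0.17) in the likely direction but -0.51 (-0.59 to -0.45) with the ratio turned. The bootstrap resampled spot pairs, which are not independent, within 1 array of replicate 2, so the intervals hold no spread between arrays. Rises and falls were chosen by the effect of replicates 1 and 3, which shares its untreated arrays with that of replicate 2. A mixture is therefore not decided at either time, although the differences at 30 min go against it. A compressed range of the array is argued against at 60 min, by a slope on the untreated level of 0.99. At 30 min this slope was 0.94 for replicate 2 and also for replicate 1. Their response slopes, which are not on a common scale, were 0.13 and 0.75. The range thus did not set replicate 2 apart from replicate 1 at 30 min, with 1 array each. A delayed response is a candidate explanation at 60 min, because the profile of replicate 2 correlated more with the 30 min than the 60 min effect of replicates 1 and 3, by 0.169 against untreated 0 min cells, by 0.0928 against untreated 60 min cells and by 0.038 to 0.169 over the 4 untreated times other than 30 min, whose arrays also enter the 30 min effect and gave 0.196. With the 0 min axis removed the differences against 0 and 60 min, the only ones recomputed, became 0.032 (0.011 to 0.056) and -0.014 (-0.035 to 0.0074). These intervals, too, come from resampling spot pairs only. A delay thus held against untreated 0 min cells but not against untreated 60 min cells. The latter comparison leans against a delay, because the untreated 60 min arrays also enter the 60 min effect of replicates 1 and 3. A delay remains undecided. The time profile does not decide on a mixture at 60 min either, which stays open also because the direction of the ratio is not settled.

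Spots a fixed distance apart responded alike. With 1 spot taken from each copy of the array, the average NaCl effects of spots 2304 positions apart correlated at 0.468 over 809 spot pairs, and those 20 positions apart at 0.172 over 1735, while 100 shuffles of the spot order reached at most 0.158 at any of 2304 offsets. The use of separate copies does not exclude position effects on the slide. The place of the spots on the slide is unknown, and some of the rows compared still lay 2304 apart. For spots 2304 positions apart, a shared ratio level is argued against by a correlation of 0.452 after its trend was removed. For spots 20 positions apart the ratio levels correlated at 0.174, as much as the effects, and a shared level was not tested there. A hypothesis is that the layout places functionally linked genes, such as members of an operon, at the distance of 2304, which may be tested once the spots are matched to genes.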
